A study of Homo sapiens with 10 samples.

How the data were processed

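RNA was measured in 10 micro-regions of formalin-fixed, paraffin-embedded human tonsil, a lymphoid organ in which B cells gather in rounded follicles and T cells in the zones between them. Per the labels' protocols, each region measured 40 μm and was taken with a mechanical picker from a section 5 μm thick, a procedure named Pick-Seq. The tissue was lysed with proteinase K, and polyadenylated RNA was captured on oligo(dT) beads. The cDNA was made and amplified with a SMART-Seq kit for ultra low input. The labels assign 5 regions to B-cell follicles, with replicates 1, 2 and 3 from follicle A and replicates 4 and 5 from follicle B, and 5 regions to a T-cell zone. How a region's site was recognised (by a stain or by shape) is not given in the sources used here.

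The authors deposited a single table of whole-number counts per Ensembl gene identifier, with 1 column per region. HISAT2 and Salmon are named per the submitters' processing notes, with the human builds GRCh38 and hg38, but neither a version nor which tool made the counts is given there. The annotation, any filter and any rounding by the authors are not given in the sources used here. No molecular identifiers are described, so reads copied in amplification count as separate reads. The intervals and floors given here cover counting error only. The table has 58735 gene rows, and each identifier was found in GENCODE release 29, from which symbols and GRCh38 coordinates were taken. The counts are per gene, so no exon or UTR can be named for a value. The strand setting of the counting is not stated, so an antisense gene cannot be told apart from its partner, and genes with near-identical copies (IGLC2 and IGLC3, TRBC1 and TRBC2) are uncertain one by one.

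Library totals ranged from 10591 to 83432 counts, which is shallow. Between 2972 and 5888 genes had at least 1 count in a library. The floor for a count of 0 was set at 3 counts. That is 36.6 in CPM (counts scaled to a common library total) in the deepest library and 249 CPM in the shallowest. Both values include the TMM scaling described below. Genes with at least 10 counts in at least 3 libraries were tested, which left 1422 of the 14966 genes with a count. These held between 55.2% and 61.3% of a library's counts. Genes that could reveal a donor's sex were left out of all tests and tables. Replicate pairs were checked for repeated libraries with a chi-square test of their counts, and the lowest chi-square per degree of freedom was 7.59, so no pair agreed within sampling noise.

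Counts were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test with the default settings of that version, TMM scaling and totals over all genes, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 5%. B-cell follicle regions were compared with T-cell zone regions in a fit of all 10 libraries. Follicle A was compared with follicle B in a fit with 3 sites, in which the T-cell zone libraries help to estimate the spread. The labels name no donor, several regions share a follicle, and the T-cell zone regions carry a single site name. Regions therefore may share a donor. The p-values over regions are too small as statements about people, and they measure only the spread between these regions. CPM values are scaled by TMM and given as mean ± SD over regions. A fold against a site with 0 counts is a lower bound computed against 3 counts over the whole site. With 1 to 3 counts at the lower site, the ratio of pooled CPM is given with its 95% exact counting interval.

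Before the data were examined, 18 gene lists were fixed from general knowledge of lymphoid tissue. They cover B cell identity, germinal centre B cells, naive or mantle B cells, T cell identity, follicular helper T cells, cytotoxic lymphocytes, plasma cells, follicular dendritic cells, fibroblastic reticular stroma, macrophages or dendritic cells, endothelium, tonsil epithelium, cell cycle, MHC class II presentation, interferon response, immediate early and heat shock genes, the mitochondrial genome and ribosomal proteins. CXCL13 stands on 2 lists, those of follicular helper T cells and of follicular dendritic cells. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and with an estimated correlation and fry beside it. For each list the count of genes is given over all genes tested and adjusted over the list alone. Also fixed then were the tests, the processing alternatives and the rule for naming genes. The rule names 19 anchor genes whatever their result, the 8 genes of smallest p in each direction among those past 5% with a count in at least 4 of the 5 regions of the higher site, the 2 tested members of smallest p of each list, and up to 4 genes past 5% in each direction between the follicles. Some genes that this rule names are not reported here. List tests between the follicles were added after seeing the data.

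Shares of counts, library totals, numbers of genes and a marker score per library were compared with exact two-sided permutation tests over the 252 assignments of 10 libraries to sites of 5, for which the smallest possible p is 0.00794. The marker score is the mean log2 CPM of the B cell identity list minus that of the T cell identity list.

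Both tests were tested on simulated data with the libraries' own depths and, for each gene, a mean pooled over all 10 libraries. For the gene test, 200 of the 1422 genes were changed. Between the sites, 15.2% of genes changed 4-fold and 65.8% of genes changed 16-fold were recovered, and 3.3% of calls were false. Between the follicles, the same shares were 3.4% and 22.8%, with 5.8% of calls false. The list test was simulated between the sites only, not between the follicles. It recovered 20 of 20 lists of 15 genes whose simulated follicle counts were multiplied by 4. Of 200 lists of 15 unchanged genes, 4% had p under 0.05. Genes were simulated independently, so this does not test the preset correlation. Estimated correlations of the real lists reached 0.365 (plasma cells, between the sites), and many real lists had fewer tested genes.

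Alternatives to this processing were other scalings (RLE, TMMwsp, totals only), other filters, a robust quasi-likelihood fit, DESeq2 1.42.0, limma-voom, removal of immunoglobulin or mitochondrial genes, a covariate for the number of detected genes, each follicle alone, the mean of both follicles, the site name as a random block, the replicate number as a block, another prior count, and leaving out each library in turn. Alternatives added after seeing the data were the newer quasi-likelihood method of edgeR (legacy = FALSE), library sizes over the tested genes, thinning without the shallowest library, and leaving out the 2 libraries richest in immunoglobulin. The setting legacy = TRUE, listed beforehand as an alternative, is the default of this edgeR version and is therefore the method used throughout. Default settings had been fixed beforehand in the belief that the newer method was the default. The newer method was run first, and the results of both were known when the actual default was kept.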

Results

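Gene expression was profiled in 10 picked micro-regions of fixed human tonsil, 5 from B-cell follicles and 5 from a T-cell zone, to compare the transcriptomes of both histological sites. The follicle libraries held 54222 ± 17183 counts (SD, n = 5) and the T-cell zone libraries 45977 ± 21548 (SD, n = 5), a difference smaller than the spread between regions (exact permutation test on log10 totals, two-sided, p = 0.579). T-cell zone replicate 4 was the shallowest library, with 10591 counts and 153 genes at 10 counts or more, while the other 9 libraries held between 40209 and 83432 counts. Genes with at least 1 count numbered 5175.8 ± 525.8 in follicles and 4810.4 ± 1088.5 in the T-cell zone (SD, n = 5 each; exact permutation test, two-sided, p = 0.627). Without T-cell zone replicate 4 the order of the site means turned round for both measures.

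**Figure D1:**
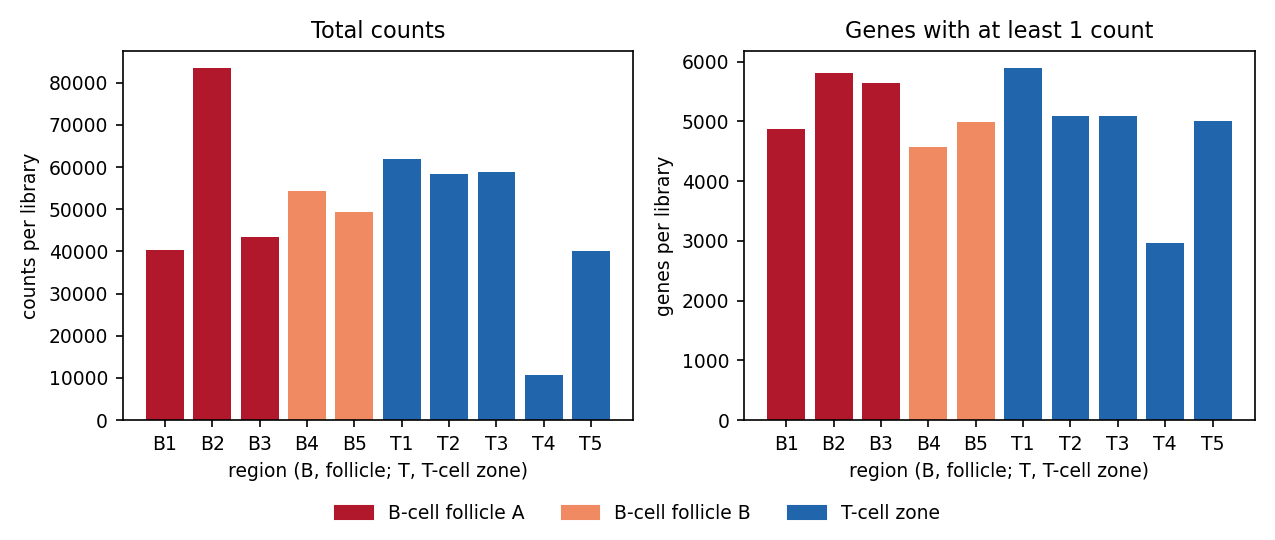
Bars give the total counts (left panel, counts per library) and the number of genes with at least 1 count (right panel) for each of the 10 regions, coloured by follicle A, follicle B or T-cell zone. T-cell zone replicate 4 holds 10591 counts and 2972 genes, and the deepest library, follicle replicate 2, holds 83432 counts.

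Regions of the B-cell follicles and of the T-cell zone differed in the genes that define their lymphocytes, their stroma and their antigen presentation. Of 17 tested genes of B cell identity, 12 were higher in follicles. MS4A1, which encodes CD20, stood at 3790 ± 1778 CPM in follicles against 24.6 ± 54.9 CPM in the T-cell zone (SD, n = 5 each). The chemokines CCL21 and CCL19, which draw CCR7-bearing cells into T-cell zones, had 683 and 318 counts in the T-cell zone and 0 in the follicles. FDCSP, a secreted product of follicular dendritic cells, and CD74, the invariant chain of MHC class II, were also higher in follicles. In all, 66 of 1422 tested genes passed 5% in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 45 of them higher in follicles and 21 higher in the T-cell zone. An unadjusted p under 0.05 was found for 203 genes. Of the 66, 31 had 0 counts at the lower site and 11 had 1 to 3 counts there.

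The marker score, the mean log2 CPM of B cell genes minus that of T cell genes, was 2.32 ± 0.35 in follicle regions and -2.20 ± 0.35 in T-cell zone regions (SD, n = 5 each), with no overlap (exact permutation test, two-sided, p = 0.00794, the smallest that 5 against 5 regions allow). It ranged from 1.74 to 2.56 in follicles and from -2.56 to -1.78 in the T-cell zone.

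**Figure D2:**
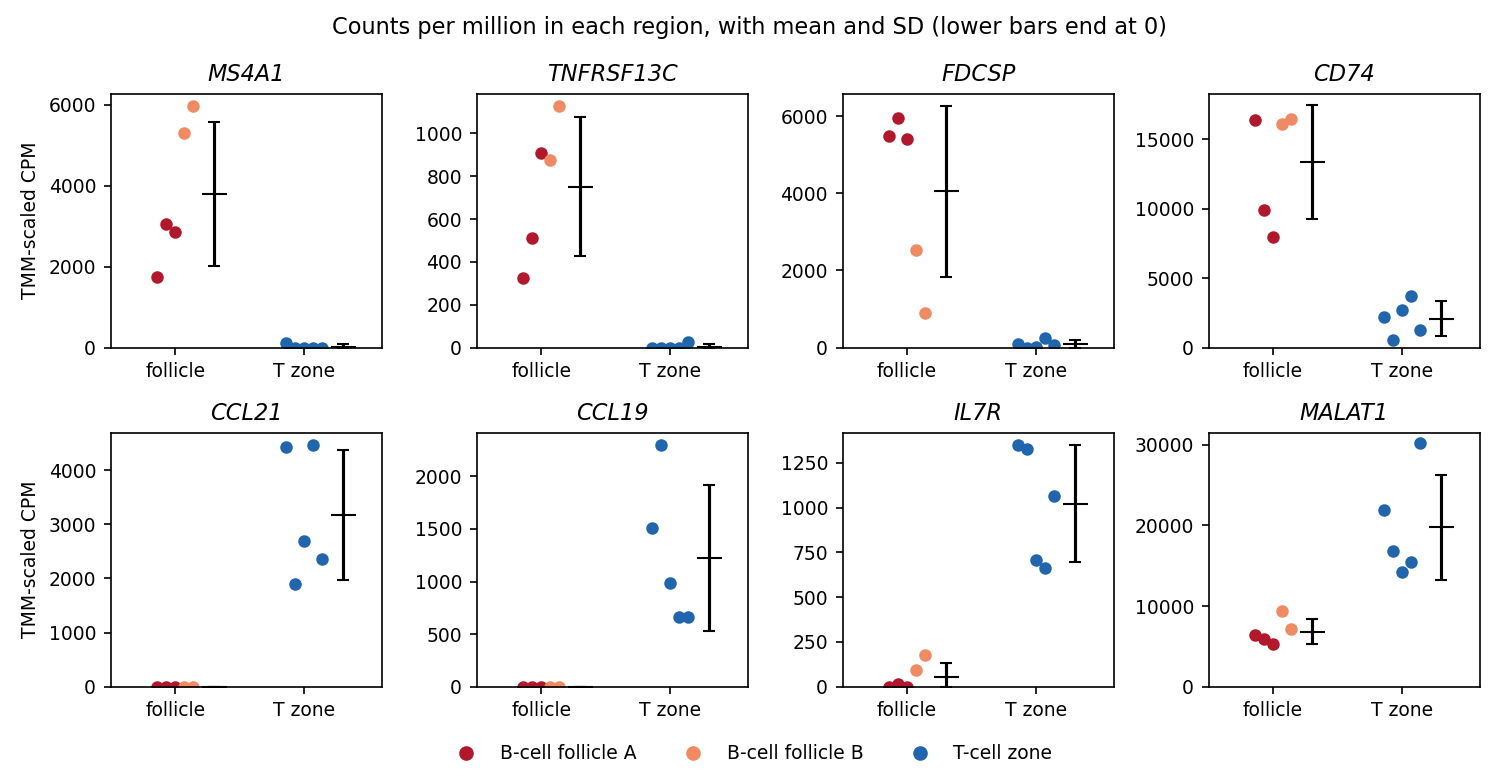
Points give TMM-scaled CPM (vertical axes, linear) of 8 genes in each region, coloured by follicle A, follicle B or T-cell zone, and the bar beside each site gives the mean and SD of its 5 regions, ended at 0 below. MS4A1, TNFRSF13C, FDCSP and CD74 lie higher in follicle regions, while CCL21, CCL19, IL7R and MALAT1 lie higher in T-cell zone regions.

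Among genes of B cell identity, 12 of 17 tested members were higher in follicles, and 15 were when adjusted over the list alone. MS4A1 (ENSG00000156738, chromosome 11, 60455752 to 60470760, GRCh38) had a log2 fold change of 6.89 ± 0.75 (SE; edgeR adjusted p = 2.74e-06). TNFRSF13C (ENSG00000159958, chromosome 22, 41922023 to 41926818), the receptor for the survival factor BAFF, had 192 counts against 1, a ratio of 167 (95% counting interval 29.6 to 6631; edgeR adjusted p = 0.000407). CD79B, a signalling chain of the B cell receptor, differed by 4.17 ± 1.08 (log2, SE; edgeR adjusted p = 0.0219), a call that ended without follicle replicate 1 (edgeR adjusted p = 0.0585). Its partner CD79A, with 56 counts against 1, did not pass (edgeR adjusted p = 0.0528). The list as a whole was higher in follicles (camera adjusted p = 1.9e-21, and 6.65e-05 with an estimated correlation). LYN (ENSG00000254087), a kinase of B cell receptor signalling outside the lists, had 174 counts in follicles and 2 in the T-cell zone, a ratio of 75.7 (95% counting interval 20.6 to 630; edgeR adjusted p = 0.00154).

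Genes of MHC class II presentation were higher in follicles for 3 of 5 tested members, and for 5 when adjusted over the list alone (camera adjusted p = 2.47e-05, and 0.00718 with an estimated correlation). CD74 (ENSG00000019582, chromosome 5, 150401637 to 150412929) stood at 13365 ± 4086 CPM in follicles and 2097 ± 1233 CPM in the T-cell zone (SD, n = 5 each), a log2 fold change of 2.69 ± 0.35 (SE; edgeR adjusted p = 2e-05). HLA-DRA, the alpha chain of HLA-DR, had 116 counts in follicles and 0 in the T-cell zone, at least 33.6-fold higher (edgeR adjusted p = 0.00489).

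Genes of follicular dendritic cells, the stromal cells that hold antigen in follicles, were higher in follicles for 3 of 10 tested members, FDCSP, CR2 and CXCL13, and for 5 when adjusted over the list alone (camera adjusted p = 0.000194, and 0.00971 with an estimated correlation). FDCSP (ENSG00000181617, chromosome 4, 70226071 to 70235252) differed by 5.90 ± 0.69 (log2, SE; edgeR adjusted p = 6.64e-06). CR2, a complement receptor that B cells also carry, stood at 2075 ± 2131.5 CPM against 45.6 ± 102 CPM (SD, n = 5 each; edgeR adjusted p = 0.00352). CXCL13, a chemokine that draws B cells into follicles, differed by 5.26 ± 1.16 (log2, SE; edgeR adjusted p = 0.00875). CXCL13 was also the single called member of 3 tested on the follicular helper T cell list, with 1 member higher at each site when adjusted over the list alone. That list's mean difference was 0.26 and its median -0.05 on the log2 scale, and its test, directed towards the T-cell zone, did not pass (camera adjusted p = 0.917).

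Germinal centre genes had 1 called member of 8 tested, MARCKSL1, and 4 when adjusted over the list alone. MARCKSL1 differed by 3.07 ± 0.89 (log2, SE; edgeR adjusted p = 0.0477). RGS13, a regulator of G-protein signalling in germinal centre B cells, had 68 counts in follicles and 0 in the T-cell zone and did not pass (edgeR adjusted p = 0.0646). BCL6, the germinal centre transcription factor, with 54 counts against 1, did not either (edgeR adjusted p = 0.0739). The list was higher in follicles with the preset correlation (camera adjusted p = 0.00707) and with fry (adjusted p = 0.0131), and did not pass with an estimated correlation (adjusted p = 0.14). Without follicle replicate 1 or 2 its camera adjusted p was 0.0549 or 0.0952. Of 6 tested naive or mantle B cell genes, TCL1A was higher in follicles, with 116 counts against 0, at least 33.6-fold (edgeR adjusted p = 0.00694). TCL1A was also the 1 member past the threshold when adjusted over the list alone. The median of this list was -0.47 and its mean 0.23 on the log2 scale, and its test, directed towards follicles, did not pass (camera adjusted p = 0.698). IL4R on the same list had 80 counts against 9 (edgeR adjusted p = 0.238).

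Plasma cell genes were higher in follicles for 3 of 7 tested members, IGKC, IGHM and JCHAIN, and for 4 when adjusted over the list alone. IGHM, the constant region of IgM, which B cells also express, differed by 4.93 ± 0.89 (log2, SE; edgeR adjusted p = 0.00154). IGKC, the kappa light chain, stood at 8809 ± 13617.5 CPM in follicles and 76.2 ± 170 CPM in the T-cell zone (SD, n = 5 each; edgeR adjusted p = 0.000655). Follicle replicate 3 alone held 1327 of its 1868 follicle counts, and with follicle B alone against the T-cell zone IGKC did not pass (edgeR adjusted p = 0.185). The list passed with the preset correlation (camera adjusted p = 0.000935) and with fry (adjusted p = 0.0146). It did not pass with an estimated correlation (adjusted p = 0.141) or without immunoglobulin genes (camera adjusted p = 0.137). Immunoglobulin genes together held 1.22 ± 1.47% of counts in follicles and 0.689 ± 1.5% in the T-cell zone (SD, n = 5 each; exact permutation test, two-sided, adjusted p = 0.54). The difference, 0.529 points, turned to -0.0983 points without follicle replicate 3 and rose to 1.20 points without T-cell zone replicate 4. In T-cell zone replicate 4 they held 3.38% (95% exact binomial interval 3.04% to 3.74%), while in the other T-cell zone libraries they held at most 0.0448%.

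Genes of T cell identity were higher in the T-cell zone for 6 of 18 tested members, IL7R, TCF7, CD3D, CCR7, GIMAP7 and LEF1, and for 10 when adjusted over the list alone (camera adjusted p = 1.85e-13, and 0.00339 with an estimated correlation). IL7R (ENSG00000168685, chromosome 5, 35852695 to 35879603), the receptor for interleukin 7, stood at 1023 ± 329 CPM in the T-cell zone and 56.2 ± 77.7 CPM in follicles (SD, n = 5 each; edgeR adjusted p = 0.00583). CD3D, a chain of the CD3 complex, differed by -4.46 ± 1.03 (log2, follicle minus T-cell zone, SE; edgeR adjusted p = 0.011), and without T-cell zone replicate 1 it did not pass (edgeR adjusted p = 0.051). CCR7, the receptor for CCL19 and CCL21, was at least 24.1-fold higher (edgeR adjusted p = 0.0177). TCF7, a transcription factor of naive and memory T cells, differed by -3.61 ± 0.82 (log2, SE; edgeR adjusted p = 0.00991). The T cell receptor constant genes TRAC and TRBC2 had 204 against 49 and 173 against 36 counts and did not pass (edgeR adjusted p = 0.122 and 0.171). Neither did CD4, with 67 against 5 (edgeR adjusted p = 0.111). T cell receptor genes together held 0.198 ± 0.0458% of counts in the T-cell zone and 0.0579 ± 0.0292% in follicles (SD, n = 5 each; exact permutation test, two-sided, p = 0.00794, adjusted p = 0.0198). CD3E, CD8A and MKI67 fell below the filter, with 9, 0 and 21 counts in follicles and 33, 16 and 6 counts in the T-cell zone.

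Of 4 tested genes of fibroblastic reticular stroma, the cells that scaffold T-cell zones, CCL21 and CCL19 were higher in the T-cell zone, also when adjusted over the list alone (2 of 4; camera adjusted p = 0.000643, and 0.0166 with an estimated correlation). CCL21 (ENSG00000137077, chromosome 9, 34709005 to 34710124) stood at 3174 ± 1206 CPM in the T-cell zone (SD, n = 5) and was at least 262-fold higher (edgeR adjusted p = 9.14e-09). CCL19 (ENSG00000172724, chromosome 9, 34689567 to 34691277) stood at 1225 ± 695 CPM (SD, n = 5) and was at least 122-fold higher (edgeR adjusted p = 1.28e-05). Both had counts in 5 of 5 T-cell zone regions.

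Outside the lists, the nuclear long non-coding RNA MALAT1 (ENSG00000251562, chromosome 11, 65497688 to 65506516) was higher in the T-cell zone, at 19748 ± 6561 CPM against 6825 ± 1566 CPM (SD, n = 5 each), a log2 fold change of -1.53 ± 0.20 (follicle minus T-cell zone, SE; edgeR adjusted p = 2e-05). The long non-coding RNA LINC00861 was at least 63.2-fold higher in the T-cell zone (edgeR adjusted p = 0.00093). GIMAP4, a GTPase of lymphocytes, had 124 counts against 3 (ratio 47.5, 95% counting interval 15.9 to 234; edgeR adjusted p = 0.00423). MAN1C1, a mannosidase, had 124 against 1 (ratio 142.5, 95% counting interval 25.1 to 5675; edgeR adjusted p = 0.00486). PRKCQ-AS1, annotated as a processed transcript and by its name antisense to the T cell kinase gene PRKCQ, was at least 32.2-fold higher (edgeR adjusted p = 0.00573). Its value is uncertain if both genes overlap, which was not checked.

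The remaining lists held no gene past 5% over all genes. Of the cytotoxic list 1 gene was tested, KLRB1, with 105 counts in the T-cell zone and 7 in follicles (edgeR adjusted p = 0.0577; 1 of 1 adjusted over the list alone). Of the macrophage or dendritic cell list 1 gene was tested, PSAP, at 538 ± 197 CPM in follicles and 163 ± 52.2 CPM in the T-cell zone (SD, n = 5 each; edgeR adjusted p = 0.263; 1 of 1 adjusted over the list alone). Of 2 interferon genes tested, 1 passed when adjusted over the list alone and 0 over all genes, and GBP2, a guanylate-binding protein, had edgeR adjusted p = 0.0809. Of 9 cell cycle genes 0 passed under either adjustment (camera adjusted p = 0.151), while without a filter the list passed towards follicles (mean 0.79 on the log2 scale, camera adjusted p = 4.66e-05). The members of smallest p were H2AFZ and CENPF (edgeR adjusted p = 0.448 and 0.557). The 3 immediate early and heat shock genes (HSPA8 and HSP90AA1 among them), the 11 mitochondrial genome genes and the 29 ribosomal protein genes tested had 0 calls under either adjustment (camera adjusted p = 0.343, 0.537 and 0.113). The ribosomal protein list passed towards the T-cell zone without a filter (camera adjusted p = 0.0142) and without T-cell zone replicate 1 (camera adjusted p = 0.0404). No endothelial or epithelial gene reached the filter, although 6 of 11 and 6 of 12 had at least 1 count. The share of counts in ribosomal protein genes was 17.3 ± 0.613% in the T-cell zone and 13.8 ± 1.66% in follicles (SD, n = 5 each; exact permutation test, two-sided, p = 0.00794, adjusted p = 0.0198). The shares of mitochondrial genome genes and of the 10 most abundant genes did not pass the exact permutation test (adjusted p = 0.54 and 0.238), and without follicle replicate 3 the mitochondrial difference, follicle minus T-cell zone, turned to 0.0163 points.

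Some calls of single genes ended in other alternatives. CCR7 did not pass without a filter, with follicle B alone or without the 2 immunoglobulin-rich libraries (adjusted p = 0.00109 to 0.185 over 26 alternatives of edgeR, DESeq2 and limma-voom). TCF7 did not pass without a filter or without those 2 libraries (0.000236 to 0.0897 over 31), and IL7R did not with follicle B alone (1.86e-05 to 0.0647 over 30). MAN1C1 and PRKCQ-AS1 also did not pass with follicle B alone (8.67e-05 to 0.176 over 26 and 2.68e-05 to 0.0749 over 29), nor CR2 with the robust fit (1.59e-15 to 0.104 over 30). CD79B also did not pass without a filter, with follicle A alone, without the 2 immunoglobulin-rich libraries or after thinning (0.000275 to 0.165 over 30). IGKC also did not with the robust fit or limma-voom (1.17e-93 to 0.185 over 30), and JCHAIN, between the sites, did not with the robust fit, DESeq2 or limma-voom (6.45e-15 to 0.976 over 24).

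**Figure D3:**
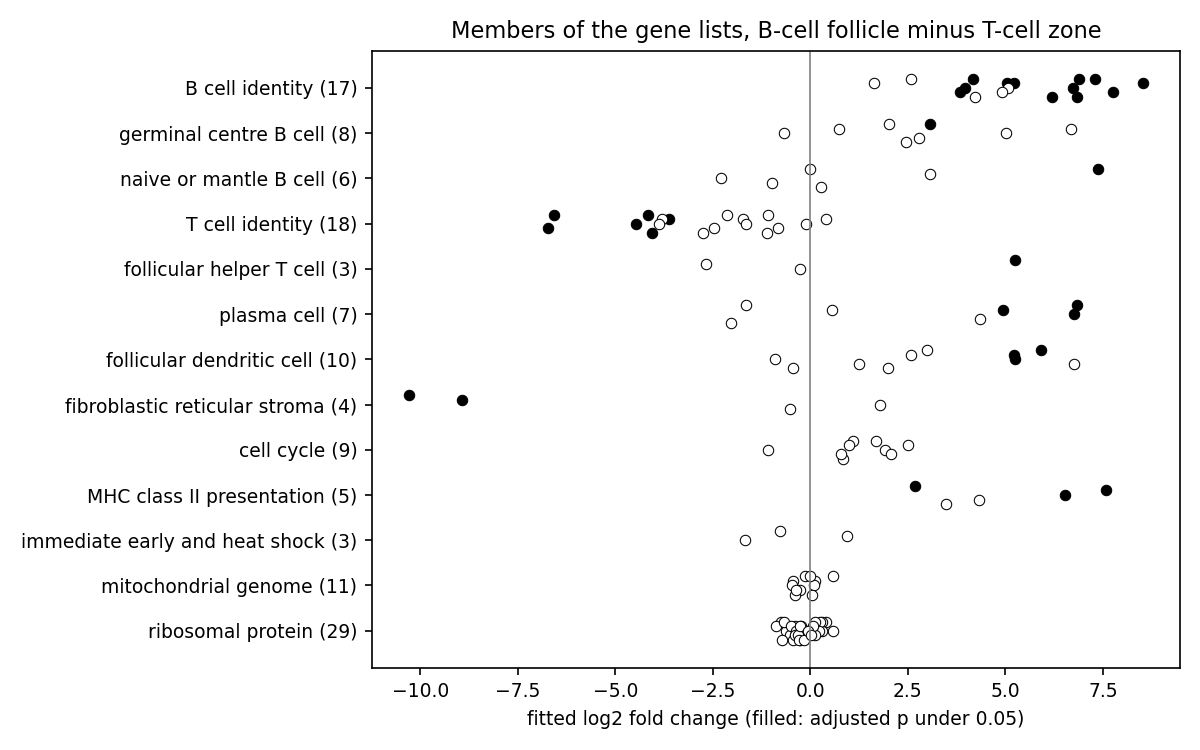
Each circle is a tested gene of a list (number tested in brackets), placed by its fitted log2 fold change, follicle minus T-cell zone, and filled where its edgeR adjusted p is under 0.05. The B cell identity list has 12 filled circles to the right of 0 and the T cell identity list 6 to the left, while fitted values of genes with 0 counts at a site depend on the prior count.

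These p-values rest on regions that may share a donor, and 3 of the 5 follicle regions share follicle A and 2 share follicle B, so they are too small as statements about people. The count of 66 genes became 38 without a filter, 104 with DESeq2 and 118 with the newer quasi-likelihood method of edgeR. With follicle B alone against the T-cell zone it became 12 of 841 tested, 1 higher in follicles and 11 in the T-cell zone. A gene found only in the 2 follicle B regions could not be tested there, since the filter asked for at least 3 libraries. The 21 genes higher in the T-cell zone became 10, 10 and 13 without T-cell zone replicates 1, 2 and 3. The call of MARCKSL1 was lost in 18 of 30 alternatives.

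Follicle A (3 regions) and follicle B (2 regions) were compared to describe how far both follicles, as named in the labels, differed. JCHAIN (ENSG00000132465, chromosome 4, 70655541 to 70681817), which encodes the chain that joins IgM and IgA into polymers, had 483 counts in follicle A, with at least 29 in each of its 3 regions, and 0 in follicle B. It was at least 97.2-fold higher in follicle A and was the single gene of 1422 past 5% (edgeR adjusted p = 0.00613), while 152 genes had an unadjusted p under 0.05. The filter asked for at least 10 counts in at least 3 libraries. A gene found only in the 2 follicle B regions could therefore not be tested, while one found only in follicle A could. This holds for list members too. Without a filter 4 genes passed, 3 higher in follicle A and 1 in follicle B. JCHAIN was also higher in follicles than in the T-cell zone (log2 fold change 6.76 ± 1.44, SE; edgeR adjusted p = 0.00645), with 0 counts in the follicle B regions, so that difference came from follicle A. With the mean of both follicles set against the T-cell zone it did not pass (log2 fold change 2.23, edgeR adjusted p = 0.976).

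Among the lists, 7 of 13 passed between the follicles with the preset correlation and 0 with an estimated correlation. Germinal centre genes (8 tested; 0 called over all genes, 3 adjusted over the list alone) were higher in follicle A by a mean of 1.61 on the log2 scale (camera adjusted p = 0.0043; adjusted p = 0.0915 with an estimated correlation, and 0.00176 with fry). RGS13 had 68 counts in follicle A and 0 in follicle B, and BCL6 had 49 and 5 (edgeR adjusted p = 0.382 and 0.651). Cell cycle genes (9 tested; 0 called, 1 adjusted over the list alone) were higher in follicle A by 1.89 (camera adjusted p = 0.0043; adjusted p = 0.0915 with an estimated correlation, and 0.0132 with fry). STMN1, a microtubule regulator named here after its values were seen, had 126 counts against 0 (edgeR adjusted p = 0.271). Without follicle replicates 1, 2 and 3 the germinal centre mean was 0.79, 1.25 and 1.26 (camera adjusted p = 0.401, 0.097 and 0.238), and without replicate 2 the cell cycle mean was 1.79 (camera adjusted p = 0.072). Plasma cell genes (7 tested; 1 called, 3 adjusted over the list alone) were higher in follicle A by 2.23 (camera adjusted p = 0.0043; adjusted p = 0.22 with an estimated correlation, and 0.0898 with fry). Without follicle replicates 1, 2 and 3 that mean was 1.06, 1.91 and 0.94 (camera adjusted p = 0.345, 0.0846 and 0.486). Naive or mantle B cell genes (6 tested; 0 called, 1 adjusted over the list alone) were higher in follicle B, with a mean of -1.42 (follicle A minus follicle B, log2; camera adjusted p = 0.0377; adjusted p = 0.247 with an estimated correlation, and 0.0842 with fry). This list did not pass without follicle replicate 2, 3, 4 or 5 (means -1.53, -1.01, -1.41 and -1.38; camera adjusted p = 0.072, 0.184, 0.061 and 0.16). FCMR, the IgM Fc receptor, named here after its values were seen, had 3 counts in follicle A and 97 in follicle B (edgeR adjusted p = 0.0902). Immediate early and heat shock genes were higher in follicle A (3 tested), and mitochondrial genome (11) and ribosomal protein (29) genes were higher in follicle B (camera adjusted p = 0.0469 for each; adjusted p = 0.22, 0.335 and 0.263 with an estimated correlation, and 0.0474, 0.0839 and 0.0517 with fry), with 0 genes called under either adjustment. The heat shock call ended without follicle replicate 2, 3 or 5 or T-cell zone replicate 4 (camera adjusted p = 0.0574 to 0.281). The mitochondrial genome call ended without follicle replicate 2, 3, 4 or 5 or T-cell zone replicate 4 (0.0574 to 0.373), and the ribosomal protein call without any follicle region or T-cell zone replicate 4 (0.0531 to 0.198).

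The lists of B cell identity (17 tested), T cell identity (18), follicular helper T cells (3), follicular dendritic cells (10), fibroblastic reticular stroma (4) and MHC class II presentation (5) did not pass between the follicles with the preset correlation (camera adjusted p = 0.873, 0.889, 0.904, 0.0885, 0.855 and 0.924). The follicular dendritic cell list, with a mean of 0.95 towards follicle A, passed with fry (adjusted p = 0.0132), without a filter (camera adjusted p = 0.0203) and without T-cell zone replicate 1 or 2 (camera adjusted p = 0.0379 and 0.0454). The mean, the median and the test differed in sign for B cell identity (-0.0034, 0.0915 and towards follicle B) and MHC class II presentation (0.0711, -0.3695 and towards follicle B). They also did for T cell identity (0.0331, 0 and towards follicle B) and follicular helper T cells (0.0009, -0.1761 and towards follicle B). Adjusted over the list alone, 1 T cell identity gene was higher in each follicle, and 0 genes of the other 5 lists passed. TRAC had 49 counts in follicle A and 0 in follicle B (edgeR adjusted p = 0.0902), while IL7R had 1 in follicle A and 13 in follicle B (edgeR adjusted p = 0.304). CR2 stood at 3228 ± 2021 CPM in follicle A (SD, n = 3) and 346 ± 208 CPM in follicle B (SD, n = 2; edgeR adjusted p = 0.382). MS4A1 stood at 2556 ± 708 CPM in follicle A (SD, n = 3) and 5639 ± 481 CPM in follicle B (SD, n = 2; edgeR adjusted p = 0.559). CD74 stood at 11431 ± 4397 CPM in follicle A (SD, n = 3) and 16266 ± 236 CPM in follicle B (SD, n = 2; edgeR adjusted p = 0.748).

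**Figure D4:**
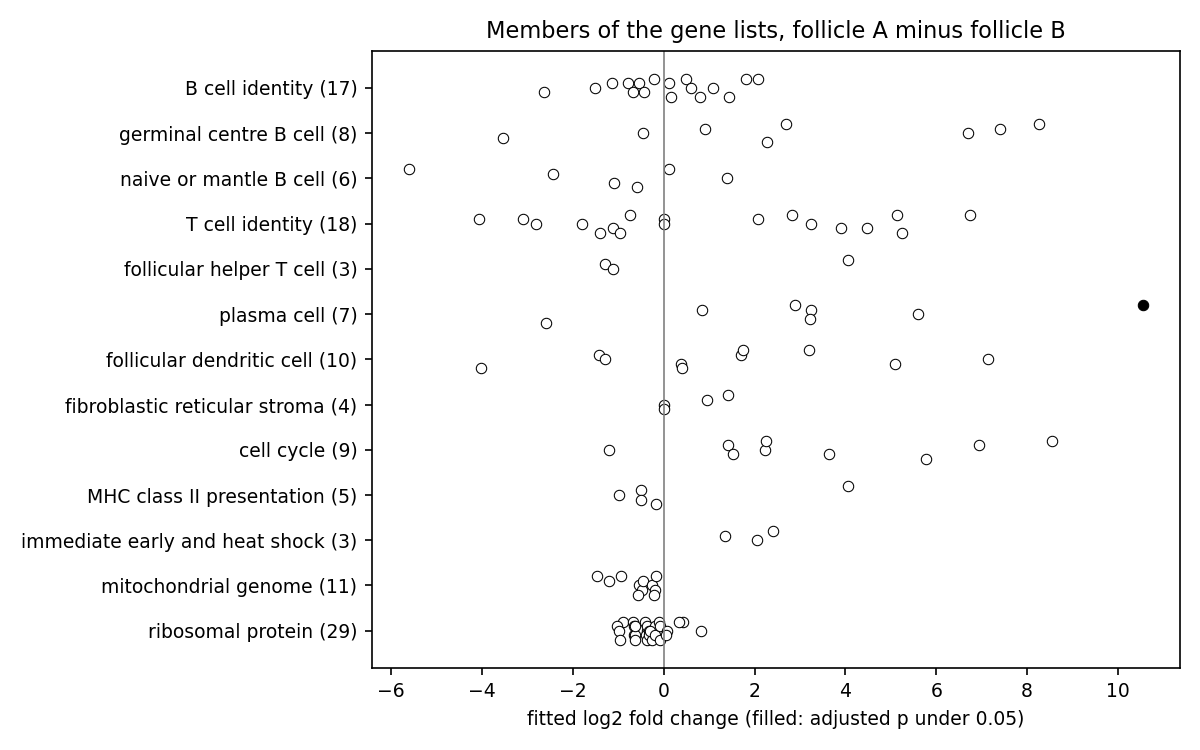
Each circle is a tested gene of a list (number tested in brackets), placed by its fitted log2 fold change, follicle A minus follicle B, and filled where its edgeR adjusted p is under 0.05. JCHAIN, at 10.55 in the plasma cell list, is the 1 filled circle, and its fitted value depends on the prior count because follicle B has 0 counts.

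With 3 against 2 regions, simulated 16-fold changes were recovered in 22.8% of genes, so a gene that did not pass is not thereby shown to be alike in both follicles. JCHAIN did not pass without follicle replicate 4 or 5 (edgeR adjusted p = 0.521 and 0.259), with the robust fit (edgeR adjusted p = 0.209) or in limma-voom (adjusted p = 0.34), and the number of lists past 5% fell to 0, 1 and 3 without follicle replicates 2, 3 and 5 and to 4 without follicle replicate 1 or 4 or T-cell zone replicate 4.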

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

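Among the tests of this part, those of carry-over, of a plasma cell, of depth for the cell cycle and mantle lists and of follicle replicate 3 were chosen after the results were seen, as was the list comparison between the follicles. The bound for follicle replicate 3 was set 3 times, each after values were seen, and its verdict differed between them. Of 110 sets of 5 regions checked for a value far from the others, 17 had one. The rate of the check, about 1 in 20, or 5.5, holds for normally distributed values. A gene with counts in a single region of a set is flagged whatever its value. The number 17 is therefore not shown to exceed chance.

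T-cell zone replicate 4 lay far from the other T-cell zone libraries in its total, with 10591 counts, and in its share of immunoglobulin genes, with 3.38%. Its immunoglobulin counts were 209 for IGLC2, 72 for IGLC3 and 68 for IGHG1, and 0 for IGKC. Random loss of reads alone was argued against, since 80 draws of the other 4 T-cell zone libraries thinned to 10591 counts reached a share of at most 0.0755%. Thinning keeps the shares of those libraries apart from sampling noise, so other effects of low input, such as uneven amplification, were not tested. Carry-over of a follicle library as a whole was also argued against. The lowest follicle ratio of IGKC to IGLC2 would bring 542 IGKC counts with that much IGLC2, and 331 with IGLC3 counted in. Carry-over of a part with another ratio, such as a lambda-chain cell, could not be tested this way. IGHG1 and IGHG4 had counts in this library (68 and 8) and in follicle replicate 3 (124 and 7), and 0 in the others. A lambda-chain plasma cell in the picked region may be the source and stays open, because JCHAIN and MZB1 together had 0 counts and XBP1 had 7 in this shallow library.

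Germinal centre and cell cycle lists were higher in follicle A and the mantle list in follicle B at the preset correlation, while with an estimated one 0 of 13 lists passed, before thinning (lowest adjusted p = 0.0915) or among these 3 after it (lowest 0.173). A difference in depth was argued against as the whole cause of the means, for the genes still tested after thinning. After thinning to 1 total without T-cell zone replicate 4 the means were 1.49, 1.74 and -1.77 (camera adjusted p = 0.0331, 0.035 and 0.0099). They covered 7, 6 and 5 genes against 8, 9 and 6 before, so the values are not directly comparable. Thinning to 40209 counts hardly changed follicle replicates 1 and 3 (40446 and 43494 before). Before thinning, follicle A totals lay on both sides of those of follicle B (54305 and 49435). The order of the regions did not rest on follicle replicate 3 alone. The summed CPM of all list members in follicle replicates 1 and 2 lay apart from both follicle B regions. The gaps were 4754 for germinal centre, 4553 for cell cycle and 1676 for mantle genes, while the ranges within either pair were at most 701, 963 and 271. With 2 regions in each pair a range is a weak measure of spread. Whether the germinal centre and mantle list results rest on replicate 3 was therefore not decided. Without replicate 3 the means were 1.26, 2.08 and -1.01 (camera adjusted p = 0.238, 0.0229 and 0.184), so that of these 3 only the cell cycle list still passed at the preset correlation with fewer regions, and without follicle replicate 1 the germinal centre mean was 0.79 (camera adjusted p = 0.401). That follicle A regions may hold more germinal centre and follicle B regions more mantle stays open. The 15 germinal centre genes below the filter summed to a mean of 2387 CPM in follicle A and 56.8 in follicle B. In the T-cell zone these genes summed to a mean of 335 CPM (34.1 to 746). The 5 such mantle genes overlapped between the follicles (163 to 428 against 399 to 658 CPM).

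The other values are given without explanation. JCHAIN differed between follicle A and follicle B, by 10.55 on the fitted log2 scale, a call that ended without follicle replicate 4 or 5 (edgeR adjusted p = 0.521 and 0.259). Follicle replicate 3 had the lowest mitochondrial share among follicles, 2.56%, and the highest CD4, 98.4 CPM. Follicle replicate 1 had 23.3 CPM of CXCL13 (1 count), and follicle replicate 4 had 54.8 CPM of MARCKSL1 (3 counts), both the lowest among follicles. Among T-cell zone regions, replicate 5 had the highest CENPF, 177.7 CPM. Single T-cell zone regions had counts where the other 4 had 0. Replicate 1 did for MS4A1 (122.8 CPM, 7 counts), CD79A (17.5 CPM, 1 count) and CR2 (228 CPM, 13 counts). Replicate 2 did for BCL6 (17.1 CPM, 1 count) and LYN (34.1 CPM, 2 counts). Replicate 5 did for CXCL13 (101.5 CPM, 4 counts), TNFRSF13C (25.4 CPM, 1 count) and IGKC (381 CPM, 15 counts). Likewise follicle replicate 2 alone had GIMAP4 (36.6 CPM, 3 counts) and follicle replicate 4 alone had MAN1C1 (18.3 CPM, 1 count) among follicle regions. Values of 3 counts or fewer lie at or below the floor, so they do not show that a region stands apart.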

How the results depend on the processing

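The settings legacy = FALSE, tested-gene library sizes, thinning, leaving out the 2 immunoglobulin-rich libraries and all list settings between the follicles were chosen after seeing the data; the cause of a change was not tested unless named. The 66 genes between the sites became 38 without a filter (14963 genes tested) and 33 with filterByExpr (616). With at least 10 counts in at least 5 libraries (598) they became 24. They became 104 with DESeq2, 41 without the 2 immunoglobulin-rich libraries and 118 with legacy = FALSE. With follicle B alone (841, fewer regions) they became 12, where genes found only in follicle B fell below the filter. When each library was left out they ranged from 45 to 77. Those of the 66 that were still tested in a setting kept their sign there. For the 31 with 0 counts at the lower site, the sign could hardly turn. Of the 66, 68.2% were higher in follicles, and 49.4% of the 83 calls of limma-voom. RLE, DESeq2 and limma-voom moved the median of the tested genes by 0.15, 0.15 and -0.13 (log2). Between the follicles, the 1 gene became 4 without a filter, 0 with filterByExpr, with the stricter filter, with the robust fit and with limma-voom, 8 with DESeq2, 2 with the covariate, 3 with legacy = FALSE and 3 after thinning, and ranged from 0 to 1 with each library left out; without a follicle A region JCHAIN fell below the filter.

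The 7 lists between the sites became 11 without a filter (18 tested; gained were cell cycle, ribosomal protein, cytotoxic and interferon) and ranged from 5 to 8 with each library left out; without follicle replicate 2 too few MHC class II genes were left to test. Between the follicles the 7 became 4 with totals only, 4 with prior count 0.5, 0 with an estimated correlation, 4 with fry (follicular dendritic cells gained, as also without a filter) and 0 to 8 with each library left out. The direction of the test turned as follows, with the list's mean given; fry and the replicate block left the mean unchanged, and only heat shock genes had passed before. Between the sites, follicular helper T cells had 0.59 with prior count 0.5, 0.26 with fry and 0.26 with the replicate block, and the mitochondrial genome had 0.0024 without the 2 immunoglobulin-rich libraries and ranged from -0.2007 to 0.0915 with each library left out. Between the follicles, without a filter follicular helper T cells had 0.46, stroma -0.17 and heat shock genes 0.14 (camera adjusted p = 0.963); with prior count 0.5 follicular helper T cells had 0.49; with fry B cell identity had -0.0034, T cell identity 0.0331 and MHC class II 0.0711. With each library left out, B cell identity ranged from -0.1623 to 0.2058, T cell identity from -0.2596 to 0.3528, stroma from -0.1395 to 1.3432, MHC class II from -0.631 to 1.3239 and follicular helper T cells from -0.5421 to 0.5624. HSP90AA1 had -0.81 (log2) with follicle B alone. The share of the 10 most abundant genes differed by -1.28 points without immunoglobulin genes (exact permutation p = 0.0476, not adjusted over the shares; 0.143 with them). With each library left out, site differences ranged from -0.0138 to 0.178 in log10 totals, from -94.2 to 634.8 in genes with a count, from -0.0983 to 1.20 points in the immunoglobulin share and from -0.489 to 0.0163 points in the mitochondrial share.

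Equal replicate numbers do not pair regions: same-number correlations ran from -0.05 to 0.09, and the replicate block gave 67 genes, 54 of them among the 66, and 7 lists. For a gene with 0 counts, the shallow library sets a floor of 249 CPM.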

Other observations

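The test of MALAT1 against other nuclear RNAs was fixed before its result was seen; those of MALAT1 against scaling and against depth were chosen after.

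Light chain counts varied between follicle regions, a difference that was not tested. The ratio of IGKC to IGLC2 counts was 2.6 in replicate 1, 2.59 in replicate 2, 20.4 in replicate 3 and 3.17 in replicate 4, and replicate 5 had 71 IGKC counts and 0 IGLC2 counts. Against IGLC2 and IGLC3 together it was 2.48, 2.5, 19, 1.18 and 4.44 in replicates 1 to 5, so the range without replicate 3 was 1.18 to 4.44. IGHG1 had 124 counts in follicle replicate 3 and 0 in the other 4 follicle regions. IGHM had counts in each of the 5 follicle regions, between 28 and 134. Cell cycle genes below the filter (18 genes) summed to between 1399 and 2382 CPM in follicle A regions and to 219 and 376 CPM in follicle B regions, with 82.9 to 1333 CPM in the T-cell zone.

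MALAT1 was 2.87 times higher in the T-cell zone by pooled CPM. Scaling was argued against, since over 5 other scalings or gene removals its log2 fold change came no closer to 0 than -1.37, and depth was argued against by -1.55 after thinning. Nuclear RNA in general may be more abundant in the T-cell zone libraries, since NEAT1, KCNQ1OT1, MIAT and PVT1 together were 1.82 times higher there (95% counting interval 1.59 to 2.08; exact permutation test on their summed CPM, two-sided, p = 0.0238). NEAT1 gave most of that, with 521 counts against 324, and PVT1 had 8 counts in follicles and 0 in the T-cell zone. Whether T cells hold more of these RNAs or nuclei were retained differently in the picked regions was not tested.

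Other splits of the 10 regions into sets of 5 and 5 were drawn, 100 in all with the real one. For the number of genes, a random grouping of these regions was argued against, since 1 of 100 splits, the real one, gave 66 genes. The highest of the others gave 2. The splits treat regions as independent, although regions share follicles and a single T-cell zone name. They therefore cannot tell a difference between the sites from a difference between the spots picked. For the number of lists, a random grouping could not be excluded, since 8 of 100 splits gave 7 or more lists past 5% and the highest of the others gave 9. The 7 others exchanged 1 region of each site, which leaves 4 of 5 together. The 80 splits that exchanged 2 gave 0 to 5 lists and at most 2 genes. Lists thus passed at the preset correlation also in groupings that mix the sites, where hardly any gene did. The splits were not run with an estimated correlation.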
